A study of Homo sapiens with 46 samples.

How the data were processed

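RNA from CD138-selected bone marrow plasma cells of 46 patients with previously untreated myeloma was measured on Affymetrix U133 Plus 2.0 arrays, 1 array per patient. Per the labels' protocols, total RNA was extracted with TRIZOL and a silica column, converted to cDNA and transcribed into biotin-labelled cRNA. Per the series' design text, samples were run singly without pooling, purity of the sort was assessed by immunofluorescence, and log2 MAS 5.0 signals were used for the GEP-70 signature. The deposited values are intensity on a linear scale, as their range shows, and each array has the same 2% trimmed mean (500.1), which MAS 5.0 global scaling gives. The scaling target and software version are not given in the sources used here. MAS 5.0 summarises each probe set within its own array, so dim probe sets are noisy on the log scale. No normalization between arrays beyond the common scale was visible, and the median signal per array ranged from 77.9 to 170.4.

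The table holds 54675 probe sets, of which 62 are controls. In the platform annotation of 2016, 41097 probe sets have 1 gene symbol, 1801 have several and 11777 have none. Only probe sets with 1 symbol were used. Symbols were checked through their gene identifiers against a RefSeq gene table of assembly GRCh38.p14, which also gave the chromosome of each gene, and no coordinates were used. Each of the 19732 genes was represented by the probe set with the highest mean. A gene was kept where at least 5 samples exceeded their own median over all probe sets, which left 16096 genes. Genes of the Y chromosome and those marking the inactive X chromosome were left out of every step.

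Values under 1 were set to 1 and log2 was taken, with no further scaling. The labels place all samples in 1 group of separate patients, and the columns of the table carry the sample names. No 2 arrays held the same values, and the best correlation of an array with another ranged from 0.838 to 0.887. The log2 ratio of the 3' to the 5' control probe sets of GAPDH and ACTB, a measure of RNA quality, was 1.64 ± 0.31 (SD, n = 46). Array batches and dates were not given, so batch could not be examined directly. In the order of the sample numbers this log2 ratio was uneven. It lay from 1.64 to 2.32 in samples 17 to 32 and from 0.90 to 1.76 in the others. Whether this marks a batch was not tested. A paired analysis does not apply, since each patient gave 1 sample.

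The partial GEP-70 score was the mean log2 signal of genes listed as higher in high-risk disease minus that of genes listed as lower. The list was recalled and not taken from a source at hand, so the score is not the published one and no threshold was applied to it. It averaged -0.97 ± 0.68 (SD, n = 46). The second signature named by the study was not computed. The proliferation score was the mean of 19 cell cycle and replication genes, each centred on its mean. Risk class, treatment arm and outcome were not used here.

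Genes were tested against each score with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), as the slope in log2 per SD of the score, with Benjamini-Hochberg adjustment and a threshold of 0.05. Members of a score were left out of its own test. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Relations between scores used Pearson's r and Spearman's rho with two-sided permutation p-values from 100000 resamples, adjusted over 24 pairs. Genes shared by both sides were left out, and r was computed again without the 2 samples farthest from the median of the first measure. Spread and coherence of the 29 lists were compared with 10000 random lists of the same size, matched on mean expression. Figures were drawn with matplotlib 3.10.9.

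The gene lists, pairs, the rule for naming genes, and the tests and alternatives not listed below as added later were fixed before the data were examined. The rule names, for each score, the 15 genes with the largest positive and the 10 with the largest negative slope among those past the threshold, up to 4 members with the smallest p in each list described, and the 20 genes with the largest SD. Immunoglobulin genes were counted and not named among the last. Samples with a gene more than 8-fold above or below its median were counted, and no groups were formed or compared. Gaps in single genes and the joint counts were looked at after the values were seen.

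The steps were tested on simulated data with 46 samples and 16096 genes, of which 200 were made to vary with a score. The test recovered 29% of genes with a slope of 0.5 SD and 100% of those with 1 SD, and 5.84% of its calls were false. Of 200 simulated pairs of unrelated values, 7.5% had a permutation p under 0.05. Weak slopes are therefore often missed at this number of samples. The alternatives tried were median centring, quantile normalization, a floor of 32, other filters and probe set rules, members scaled to unit SD, removal of the 2 farthest samples, and RNA quality or other-cell markers as covariates. The other-cell covariate averaged monocyte, granulocyte, erythroid and T and NK markers, without stromal or megakaryocyte markers. For the GEP-70 score, proliferation was also left out of the score or used as a covariate. Leaving out each sample in turn, quantile normalization for the chromosome comparison, and the tests of what lowers the other-cell markers were added after the data were seen.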

Results

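Gene expression was measured in plasma cells from the bone marrow of 46 patients with multiple myeloma, a cancer of antibody-secreting plasma cells. The marrow was taken before any treatment, at entry to a trial of lenalidomide with dexamethasone, and cells carrying CD138 (syndecan-1, a plasma cell surface protein) were selected with magnetic beads. Each patient's cells were hybridised to 1 array, and the labels place all 46 samples in 1 group. The study asked how expression-based risk relates to this therapy, but risk class, treatment arm and outcome were not used here. Expression was therefore compared across samples along continuous scores, and no samples were split into risk groups. The 2% trimmed mean signal was 500.1 on each array, and the median signal ranged from 77.9 to 170.4. The number of arrays limits the precision of every slope and correlation.

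The 12 measured genes of plasma cell identity had SDs between 0.42 and 1.19 on the log2 scale across the samples, with DERL3 at the upper end. SDC1, which encodes CD138, had a log2 signal of 14.19 ± 0.58 (SD, n = 46), and TNFRSF17, the receptor BCMA, 15.33 ± 0.44 (SD, n = 46). XBP1, the transcription factor of the secretory programme, was at 15.34 ± 0.59 and IRF4, a survival factor of plasma cells, at 12.93 ± 0.66 (SD, n = 46). Among genes of other marrow cells, the SD between samples was 2.06 for the neutrophil gene S100A9, 2.11 for the monocyte gene LYZ and 1.59 for the haemoglobin gene HBB. Levels of different probe sets are not comparable with each other and low signals lie near background, so these values do not give the share of each cell type.

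FGFR3 and NSD2, neighbouring genes activated together by a recurrent immunoglobulin translocation in myeloma, were each high in part of the samples. FGFR3 lay between 15.64 and 16.55 (log2) in 7 samples and at or below 8.99 in the other 39. NSD2 lay at or above 12.16 in 10 samples and at or below 9.52 in the other 36, and the 7 samples with high FGFR3 were all among these 10. CCND2, a D-type cyclin of the cell cycle, was at or above 13.18 in 22 samples and at or below 8.51 in 24. All 10 samples with high NSD2 were among the 22 with high CCND2. These counts describe gaps in the measured values, and no test was applied to them.

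CCND1, another D-type cyclin, was at or above 15.15 in 2 samples, neither of which had high CCND2. It was more than 8-fold below its median in 12 samples, all of which had high CCND2. MAF, a transcription factor and a further translocation target, was more than 8-fold above its median in 3 samples, and ITGB7, an integrin subunit induced by MAF, in 4. These 3 and 4 samples all had high CCND2, and 2 samples were counted for both genes. They were not a set apart from the samples with high NSD2, which held 2 of the 3 and 3 of the 4. CCND3 and MYC exceeded their medians 8-fold in 0 samples.

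**Figure D1:**
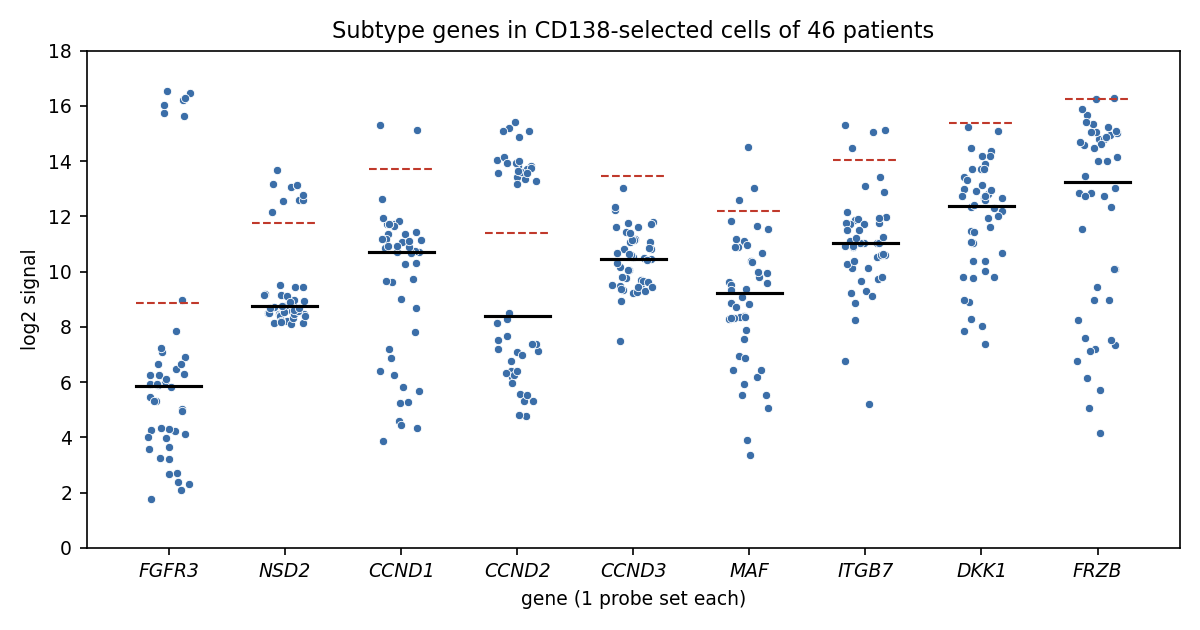
Log2 signal of 9 subtype genes, 1 point per sample (n = 46), with the median of each gene as a black bar and the level 8-fold above it as a dashed red line. FGFR3, NSD2 and CCND2 show a gap, with 7, 10 and 22 samples above it, whereas CCND3 and DKK1 have no sample above the dashed line.

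Cancer-testis antigens, normally restricted to germ cells, differed widely between samples but showed no gap like that of NSD2 (2.63 log2). Within each gene the largest gap was 2.08 for SSX1, which set 1 sample apart, 1.25 for MAGEC1 and 1.21 for MAGEC2. It was 1.12 for MAGEA1 and 1.01 for MAGEA6. MAGEA1 was more than 8-fold above its median in 10 samples, MAGEA6 in 9, and MAGEC2 and SSX1 in 4 each. MAGEA6 also lay more than 8-fold below its median in 10. The medians of MAGEA1 (5.67) and SSX1 (6.42) were low, where log2 signals are noisy. MAGEC1, whose median was 10.32, had no such sample and lay more than 8-fold below its median in 7. LAMP5, used to tell subtypes apart, was more than 8-fold above its median in 12 samples and more than 8-fold below it in 9. FRZB, a secreted inhibitor of Wnt signalling, was more than 8-fold below its median in 16. In all, 17 of the 22 genes examined had at least 1 sample more than 8-fold above the median. These 17 include GAGE1, whose probe set did not pass the filter on dim genes (median 3.46, maximum 7.16), so its 4 samples are not evidence of expression. MAGE, GAGE and SSX genes have near-identical relatives. With probe sets that can detect related transcripts (_x_at and _s_at) left out, 15 of the 22 genes could still be measured and 10 had such a sample: of the 17, 6 (CCND2, FGFR3, MAGEA1, MAGEA6, MAGEA12 and SSX1) had no other probe set, and MAGEC2 was measured but no longer had one.

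The 20 genes that differed most between patients included 4 of these 22. By SD of log2 signal the first were FGFR3 (4.34), CCND2 (3.84), AGR2 (3.74), SHISA2 (3.74), ESRP1 (3.62), FRZB (3.59), NES (3.56), RGS13 (3.54), NLGN4X (3.48) and LAMP5 (3.48). NAP1L2, BBOX1, CRIP1, RUNX2, UCHL1, TMEM132D-AS1, AZGP1, NOL4, GPAT2 and DSG2 followed, with SDs from 3.47 down to 3.22. 1 immunoglobulin gene would also have been among the top 20. The median SD over the 16096 genes was 0.82 and the 90th percentile 1.52.

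Of 29 gene lists fixed before the data were examined, 15 had a median SD above the 97.5th percentile of random lists matched on size and mean expression. These were translocation targets with D cyclins (median SD 2.41), cancer-testis antigens (2.33), immunoglobulins (2.04), subtype-associated genes (1.96), interferon response (1.71), glucocorticoid response (1.25), NF-kB targets (1.22), proliferation (1.14), immediate early genes (1.08), and the markers of granulocytes (2.06), stroma (1.96), monocytes and macrophages (1.93), B cells (1.69), megakaryocytes and platelets (1.49) and erythroid cells (1.37). Respiratory chain genes varied less than nearly all random lists, with a median SD of 0.40 at percentile 0.39. The lists of p53 targets (0.79), GEP-70 high-risk genes (0.66), GEP-70 low-risk genes (0.65), the long arm of chromosome 13 (0.63), ribosome biogenesis (0.61), plasma cell identity (0.58), the long arm of chromosome 1 (0.56), the endoplasmic reticulum and unfolded protein response (0.50), proteasome (0.50), lenalidomide targets (0.47), housekeeping genes (0.46) and ribosomal proteins (0.44) lay within the range of random lists, as did T and NK cell markers (1.30). For ribosomal proteins this depended on the scaling: they were at percentile 12.1, against 0.4 with arrays centred on their median and 0.01 after quantile normalization, where their median SD was 0.24. Of the 15 lists, B cell and erythroid markers fell below the bound with the mean over probe sets. Without _x_at and _s_at probe sets, stromal, megakaryocyte and erythroid markers did and cancer-testis antigens were not tested.

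Genes within a list moved together in 22 of the 29 lists, with a mean pairwise correlation above the 97.5th percentile of matched random lists. Ribosomal proteins had a mean pairwise r of 0.813 (0.358 after quantile normalization), interferon response genes 0.672, proliferation genes 0.645, granulocyte markers 0.642, erythroid markers 0.625 and monocyte and macrophage markers 0.552. Genes of the long arm of chromosome 1 had 0.484, NF-kB targets 0.463 and genes of the long arm of chromosome 13 0.340. The 7 lists below the bound were the translocation targets with D cyclins (0.0813), plasma cell identity (0.0762), p53 targets (0.0658), glucocorticoid response (0.0619), lenalidomide targets (0.0570), housekeeping genes (0.0416) and B cell markers (-0.00581). With arrays centred on their median 18 lists stayed above the bound, and GEP-70 low-risk, subtype-associated, unfolded protein response and immunoglobulin genes did not. Without _x_at and _s_at probe sets 17 of the 22 stayed above it: unfolded protein response, ribosome biogenesis, proteasome and stromal genes did not, cancer-testis antigens were not tested, and p53 targets came to lie above it.

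Many genes varied with an expression score of risk. The score was the mean of genes higher minus the mean of genes lower in high-risk disease, from the GEP-70 signature the study used. That list was written from memory and is partial (44 and 9 genes measured), so the published risk threshold was not applied. Among genes outside the list, AZGP1, a secreted glycoprotein, rose by 1.82 ± 0.40 log2 per SD of the score (SE, n = 46; limma adjusted p = 0.00426). PTPRCAP, which binds the phosphatase CD45, rose by 1.72 ± 0.38, the serotonin receptor HTR2C by 1.58 ± 0.34, the trophoblast glycoprotein TPBG by 1.43 ± 0.30 and the kinetochore gene NUF2 by 1.18 ± 0.18. The protease inhibitors SERPINE2 (1.32) and TIMP1 (1.23), the protease ADAMTS1 (1.23), the IgM receptor FCMR (1.26), and TMEM255A (1.34), GOLM1 (1.27), NAP1L3 (1.26), SHROOM3 (1.21), LINC00484 (1.21) and GAS1 (1.17) rose as well. Without the 2 samples farthest from the median score AZGP1, PTPRCAP, TPBG and NUF2 kept the call and the other 11 of these 15 genes lost it. All slopes without such samples, here and below, are per SD of the remaining ones, which is smaller than over all 46. Slopes per SD of the remaining samples ranged among these 11 from 1.30 for HTR2C (adjusted p = 0.0506) and 1.24 for GOLM1 (adjusted p = 0.0827) to 0.50 for LINC00484 (adjusted p = 0.382).

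Genes that fell as the score rose included KLHL14, at -1.51 ± 0.39 log2 per SD (SE, n = 46; limma adjusted p = 0.0148), and the neuronal enolase ENO2, at -1.32 ± 0.15 (limma adjusted p = 6.20e-07). The growth factor receptor KIT had a slope of -1.21 ± 0.38 and the ligand WNT4 -1.23 ± 0.29. MPO, the myeloperoxidase of neutrophil precursors, had a slope of -1.08 ± 0.27 and CTSW, a protease of T and NK cells, -1.16 ± 0.34. GNG11 (-1.31), CCDC85A (-1.20), SOWAHC (-1.18) and MFAP3L (-1.14) also fell. Of these 10 genes ENO2, WNT4, SOWAHC and MFAP3L kept the call without the 2 samples, ENO2 with a slope of -0.72. KLHL14 (-0.97, adjusted p = 0.224), KIT (-0.43, adjusted p = 0.629), CCDC85A (-0.72, adjusted p = 0.339), GNG11 (-0.95), CTSW (-1.08) and MPO (-0.80) lost it. Probe sets of GAS1, SHROOM3 and WNT4 disagreed: 2 of 3 probe sets of GAS1 and 1 of 3 of each of the others had a slope of the opposite sign.

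Over all 16043 genes tested, 530 rose and 357 fell with the partial GEP-70 score (limma, Benjamini-Hochberg adjusted p under 0.05). The share of rising genes among those called was 59.8%, against 79.2% with arrays centred on their median and 64.7% after quantile normalization. Without the 2 samples farthest from the median score 106 rose and 63 fell, and 157 of these 169 genes were among the 887 called. All 887 kept the sign of their slope there, with a median of 80.5% of its size per SD of the remaining samples. That SD is smaller, so the share kept per unit of score was larger for these genes. These genes were chosen in data that include the remaining samples, so a kept sign is close to given. Without the sample with the highest proliferation score, the only one to move the total by over 1.5 times, 220 rose and 155 fell. With the proliferation score as a covariate 8 rose and 14 fell, and the slope of KIT became 0.12 (adjusted p = 0.969). With the 3 of the 44 high-risk genes that are also in the proliferation list left out of the score, 532 rose and 375 fell. Other cell cycle genes, such as ASPM and KIF14, stayed in the score.

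Proliferation genes rose with the partial GEP-70 score, by a median of 0.71 log2 per SD with shared members left out. All 16 measured members rose, both over all genes and adjusted over the list alone. The replication genes MCM2 (0.67 ± 0.09, SE, n = 46) and TYMS (0.85 ± 0.12), the mitotic cyclin CCNB2 (0.79 ± 0.12) and the kinetochore gene ZWINT (0.86 ± 0.11) were among them. The list was called by camera (adjusted p = 7.61e-32), also with an estimated correlation between genes (adjusted p = 0.00126). The score itself kept its cell cycle genes, among them the shared members, so part of this rise is built in.

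Genes of the 1q21-q22 region, a part of chromosome 1 often gained in myeloma, rose as a list by a median of 0.23 log2 per SD. Of 15 measured members 7 rose, and 10 did so adjusted over the list alone, with ILF2 (0.36 ± 0.07, SE, n = 46), SETDB1 (0.34 ± 0.08), SSR2 (0.21 ± 0.06) and ANP32E (0.29 ± 0.08) first. Camera gave an adjusted p of 5.29e-10 (adjusted p = 0.101 with an estimated correlation). CKS1B and PSMD4 of this region stayed in the score, so part of this rise may be built in. Proteasome genes rose by a median of 0.16 (adjusted p = 0.000372, and adjusted p = 0.160 with an estimated correlation). Of 11 members PSMC4 (0.23 ± 0.06) alone rose over all genes, and 4 rose adjusted over the list alone. Cancer-testis antigens were called as well (median 0.55, adjusted p = 0.0482, and adjusted p = 0.395 with an estimated correlation), with MAGEA1 (1.15 ± 0.35) the 1 of 6 members that rose, by either adjustment. That call was lost without the 2 samples farthest from the median score (adjusted p = 0.396).

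Ribosomal protein genes fell as a list as the partial GEP-70 score rose, by a median of 0.17 log2 per SD. RPL3 (-0.27 ± 0.07, SE, n = 46), RPS6 (-0.18 ± 0.05) and RPS14 (-0.17 ± 0.05) fell, 3 of 8 members over all genes and 5 adjusted over the list alone. Camera gave an adjusted p of 0.000128 (adjusted p = 0.395 with an estimated correlation).

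Markers of other marrow cells also fell as lists: monocytes and macrophages by a median of 0.49 log2 per SD (adjusted p = 0.0130), granulocytes by 0.46 (adjusted p = 0.0218) and stroma by 0.37 (adjusted p = 0.0477). With an estimated correlation the adjusted p was 0.395, 0.546 and 0.395. Of their 7, 10 and 7 members MPO was the only one to fall over all genes. Adjusted over the list alone, 1 monocyte marker, 1 granulocyte marker and 0 stromal markers fell. CSF1R (-0.47 ± 0.16, SE, n = 46; limma adjusted p = 0.0691), LTF (-0.80 ± 0.38; 0.224) and COL1A1 (-0.79 ± 0.28; 0.0937) did not pass over all genes. The 3 list calls were lost without the 2 samples farthest from the median score (adjusted p = 0.258, 0.167 and 0.0753). A score of other-cell markers averaged the monocyte, granulocyte, erythroid and T and NK lists, without stromal or megakaryocyte markers. The score of other-cell markers had an r of -0.311 with the risk score (permutation p = 0.0346, adjusted p = 0.0923 over 8 technical relations; rho -0.260, permutation p = 0.0807), and -0.152 without those 2 samples. It rose with the median signal of the array (r = 0.613, adjusted permutation p = 8e-05; rho 0.513, adjusted p = 0.00312) and, by r, with the 3'/5' ratio of the control probe sets (r = 0.413, adjusted permutation p = 0.0162; rho 0.249, adjusted p = 0.191). Without _x_at and _s_at probe sets the proliferation and 1q21-q22 lists alone stayed called with the partial GEP-70 score. There the adjusted p was 0.381 for ribosomal proteins (3 members left), 0.327 for proteasome, 0.127 for monocyte, 0.0839 for granulocyte and 0.139 for stromal genes, and cancer-testis antigens were not tested.

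The remaining lists were not called with the partial GEP-70 score. Translocation targets with D cyclins had a median slope of 0.71 (adjusted p = 0.0758). Their member NSD2 passed the test (1.01 ± 0.22, SE, n = 46; adjusted p = 0.00378), but its values form separate sets, so no graded relation can be read from the slope. Among subtype-associated genes (median 0.30, adjusted p = 0.305) ITGB7 rose by 0.89 ± 0.25. Its log2 signal was 15.12 and 14.48 in the 2 samples with the highest score, against a median of 11.05. The slope without these 2 samples is not given here. The glucocorticoid receptor NR3C1, through which dexamethasone acts, fell by 0.31 ± 0.08 (limma adjusted p = 0.0149), in a list with a median of -0.13 (adjusted p = 0.166). The chaperone PDIA4 rose by 0.33 ± 0.09, CAB39L on chromosome 13 fell by 0.36 ± 0.07, and HPRT1 of the housekeeping list rose by 0.26 ± 0.07.

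List medians with the same score were -0.06 for the long arm of chromosome 13 (adjusted p = 0.385), -0.04 for plasma cell identity (0.226), -0.04 for the unfolded protein response (0.693), -0.24 for immunoglobulins (0.226), 0.02 for lenalidomide targets (0.803), -0.19 for NF-kB targets (0.0617), -0.02 for interferon response (0.998) and 0.05 for ribosome biogenesis (0.520). They were 0.05 for the respiratory chain (adjusted p = 0.123), 0.12 for p53 targets (0.520), -0.02 for immediate early genes (0.520), -0.40 for erythroid (0.166), 0.02 for T and NK (0.693), 0.04 for B cell (0.915) and -0.43 for megakaryocyte markers (0.0617), and 0.02 for housekeeping genes (0.504). For interferon, T and NK cell and B cell genes the mean slope and the test had the opposite sign to the median.

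**Figure D2:**
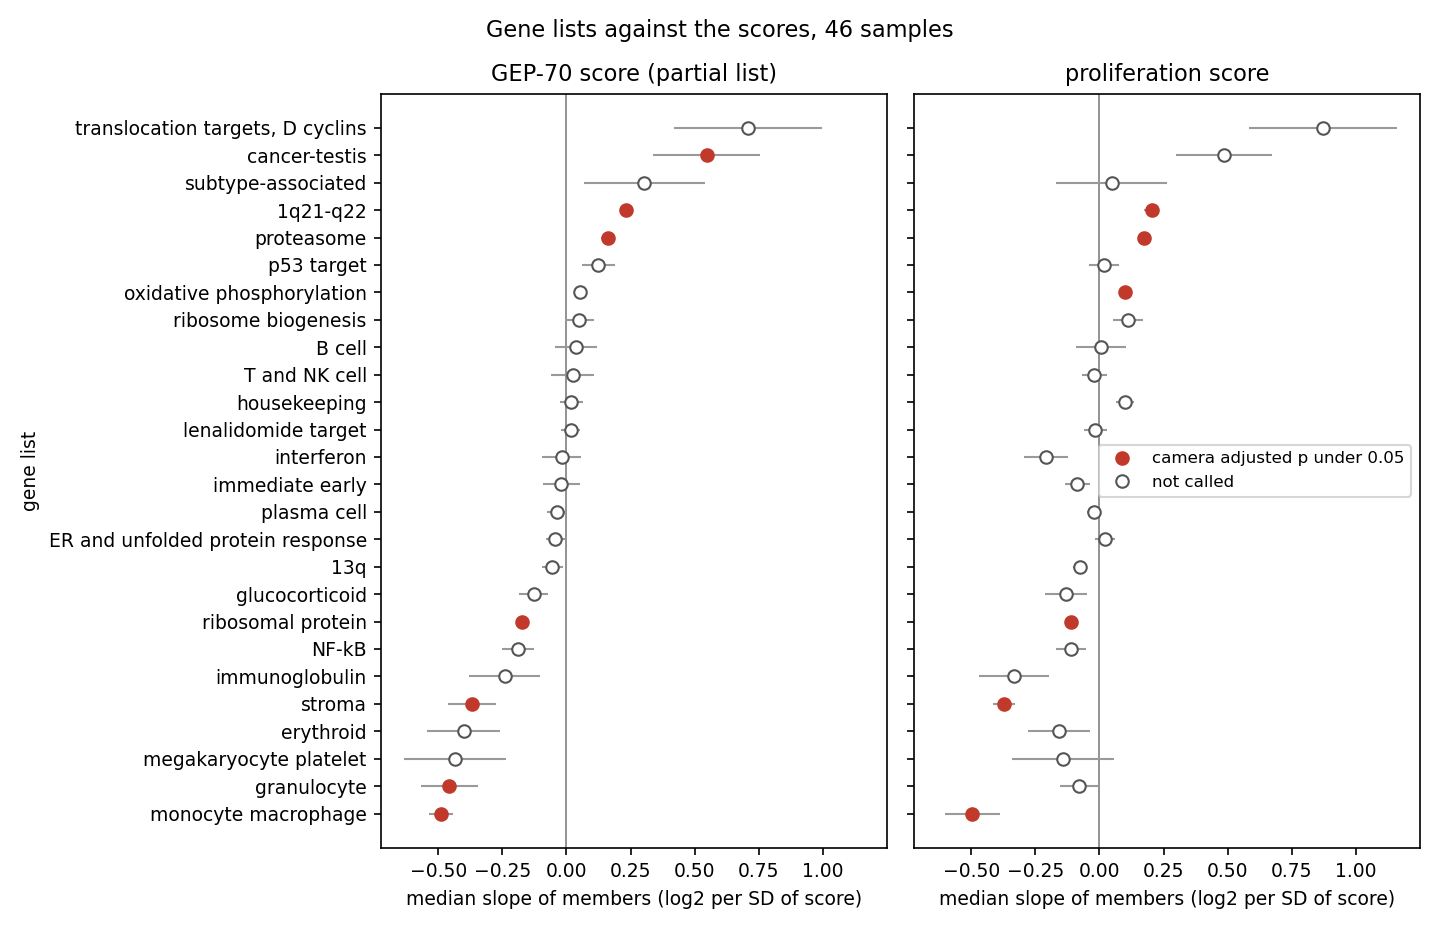
Median slope of the members of each gene list (log2 per SD of the score, n = 46). The partial GEP-70 score is on the left and the proliferation score on the right. Lines are ±1 SE of the mean slope of the members, drawn around the median. Filled red points are lists with a camera adjusted p under 0.05. The 3 lists that form the scores are not drawn, and monocyte and macrophage markers lie at -0.49 and -0.50.

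Genes that rose with the proliferation score included further cell cycle genes. DTL, which acts in DNA replication control, rose by 1.37 ± 0.12 log2 per SD (SE, n = 46; limma adjusted p = 6.90e-11), and SHCBP1 rose by 1.33 ± 0.12. NUF2 rose by 1.33 ± 0.16, the centrosome kinase NEK2 by 1.24 ± 0.15 and the mitotic motor KIF4A by 1.18 ± 0.14. DSG2, a desmosomal cadherin and itself a GEP-70 gene, rose by 1.58 ± 0.41. AZGP1 (1.47), HTR2C (1.44), TPBG (1.31), MPPED2 (1.27), SHROOM3 (1.25), C1orf21 (1.19), LRP12 (1.18), GAS1 (1.16) and ZNF503 (1.15) completed the 15 with the steepest rise, of which 10 kept the call without the 2 samples farthest from the median score and MPPED2 (0.93), SHROOM3 (1.03), C1orf21 (1.06), GAS1 (1.04) and ZNF503 (0.93) lost it.

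KIT had the steepest fall with the proliferation score, at -1.65 ± 0.34 log2 per SD (SE, n = 46; limma adjusted p = 0.00196). KLHL14 followed at -1.49 ± 0.39, GNG11 at -1.28 ± 0.36, the protease TMPRSS11E at -1.23 ± 0.26 and CTSW at -1.22 ± 0.34. The adaptor STAP1 (-1.12), WNT4 (-1.10), the granzyme B inhibitor SERPINB9 (-1.06), the pseudogene ANKRD36BP2 (-1.05) and TNFSF8, the ligand of CD30 (-0.98), fell too. Without the 2 samples TMPRSS11E, STAP1 and WNT4 kept the call, STAP1 with a slope of -0.71. KIT (-1.03, adjusted p = 0.129), KLHL14 (-1.37), GNG11 (-1.15), CTSW (-1.18), SERPINB9 (-0.52), ANKRD36BP2 (-0.45) and TNFSF8 (-0.85) lost it. ANKRD36BP2 has close relatives, so its signal is uncertain. For ZNF503, 3 of 4 probe sets had a slope of the opposite sign to the one used, and for TPBG, SHROOM3, C1orf21, GAS1 and WNT4 1 probe set did.

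Over 16077 genes, 372 rose and 151 fell with the proliferation score (limma adjusted p under 0.05), a rising share of 71.1%, against 92.4% with arrays centred on their median and 75.5% after quantile normalization. Median centring raised the number of rising genes to 1343. With the 2 samples farthest from the median score left out 144 rose and 34 fell, and 157 of these 178 genes were among the 523. All 523 kept the sign of their slope, with a median of 80.6% of its size per SD of the remaining samples. Here too that SD is smaller, so the share kept per unit of score was larger. This comparison too reuses samples in which the genes were chosen. Without the sample with the highest score alone, 151 rose and 32 fell. Among the 16027 genes tested against both scores 338 were called with each, all in the same direction, against 27.6 for independent lists. The scores share members and had an r of 0.764 with each other, so this overlap is not independent evidence. The 3'/5' ratio of the control probe sets had an r of 0.229 with the proliferation score (permutation p = 0.127, adjusted p = 0.203; rho 0.313, permutation p = 0.0355, adjusted p = 0.142), and 0.317 without 2 samples.

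GEP-70 high-risk genes rose with the proliferation score by a median of 0.26 log2 per SD with shared members left out. Of 41 measured, 15 rose, among them the mitotic genes ASPM (0.85 ± 0.11, SE, n = 46), KIF14 (0.88 ± 0.11) and CENPW (0.51 ± 0.08) and the replication factor RFC4 (0.39 ± 0.06). Adjusted over the list alone, 27 rose and 1 fell. Camera called the list (adjusted p = 3.62e-21), also with an estimated correlation (adjusted p = 1.31e-06). GEP-70 low-risk genes fell as a list, by a median of 0.15 (adjusted p = 0.0101, and adjusted p = 0.327 with an estimated correlation). Of these 9 genes 0 fell over all genes and 1 adjusted over the list alone, and LTBP1 had a slope of -0.45 ± 0.13 (limma adjusted p = 0.0517).

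The 1q21-q22 genes rose with the proliferation score as well, by a median of 0.20 log2 per SD. Of 17 members 5 rose, with the cell cycle regulator CKS1B first (0.62 ± 0.10, SE, n = 46), and 13 rose adjusted over the list alone. Camera gave an adjusted p of 1.45e-11 (adjusted p = 0.0750 with an estimated correlation). Proteasome genes had a median of 0.17 and an adjusted p of 8.34e-05 (adjusted p = 0.0750 with an estimated correlation), with 0 of 11 rising over all genes and 5 adjusted over the list alone. Respiratory chain genes had a median of 0.10 and an adjusted p of 0.0101 (adjusted p = 0.368 with an estimated correlation). CYC1 (0.21 ± 0.06) was the 1 of 11 that rose, with 2 adjusted over the list alone. That call was lost without the 2 samples farthest from the median score (adjusted p = 0.584).

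Ribosomal protein genes fell as a list with the proliferation score by a median of 0.11 log2 per SD (adjusted p = 0.00865), monocyte and macrophage markers by 0.50 (adjusted p = 0.0349) and stromal markers by 0.37 (adjusted p = 0.0413). With an estimated correlation the adjusted p was 0.511, 0.511 and 0.368. Of their members 0 fell over all genes, and adjusted over the list alone 1 monocyte marker did. Without the 2 samples farthest from the median score the monocyte and stromal calls were lost (adjusted p = 0.520 and 0.227). Without _x_at and _s_at probe sets the high-risk, low-risk, 1q21-q22 and respiratory chain lists stayed called with the proliferation score. Ribosomal protein (adjusted p = 0.262), proteasome (0.160), monocyte (0.0743) and stromal genes (0.160) were not.

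The other lists were not called with the proliferation score. Their medians were -0.08 for the long arm of chromosome 13 (adjusted p = 0.247), 0.87 for translocation targets with D cyclins (0.0760), 0.05 for subtype-associated genes (0.905), -0.02 for plasma cell identity (0.446), 0.02 for the unfolded protein response (0.905), -0.33 for immunoglobulins (0.302), -0.02 for lenalidomide targets (0.643), -0.13 for glucocorticoid response (0.213), -0.11 for NF-kB targets (0.291) and -0.21 for interferon response (0.331). They were 0.49 for cancer-testis antigens (adjusted p = 0.208), 0.11 for ribosome biogenesis (0.336), 0.02 for p53 targets (0.874), -0.09 for immediate early genes (0.247), -0.08 for granulocyte (0.839), -0.16 for erythroid (0.444), -0.02 for T and NK (0.874), 0.01 for B cell (0.847) and -0.14 for megakaryocyte markers (0.247), and 0.10 for housekeeping genes (0.268). For subtype-associated, lenalidomide target and B cell genes the median and the mean slope had opposite signs.

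High-risk genes were closely related to proliferation genes across the samples. With shared genes left out, the scores of the GEP-70 high-risk and proliferation lists had an r of 0.852 (permutation p = 1e-05, the smallest 100000 resamples can give; adjusted p = 0.00012) and a rho of 0.816 (permutation p = 1e-05). Without the 2 samples farthest from the median, r was 0.808. The high-risk list still held cell cycle genes such as ASPM, KIF14, CENPW and RFC4, so part of this relation follows from what the lists contain. High-risk genes and 1q21-q22 genes had an r of 0.639 (adjusted permutation p = 0.00012) and a rho of 0.472 (permutation p = 0.00117), with r falling to 0.451 without the 2 samples. Only CKS1B and PSMD4, which are on both lists, were left out there. High-risk genes elsewhere on chromosome 1 were not, so part of this relation may be built in. Proliferation and 1q21-q22 genes had an r of 0.556 (adjusted permutation p = 0.00024) and a rho of 0.386 (permutation p = 0.00808), and r was 0.433 without the 2 samples.

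**Figure D3:**
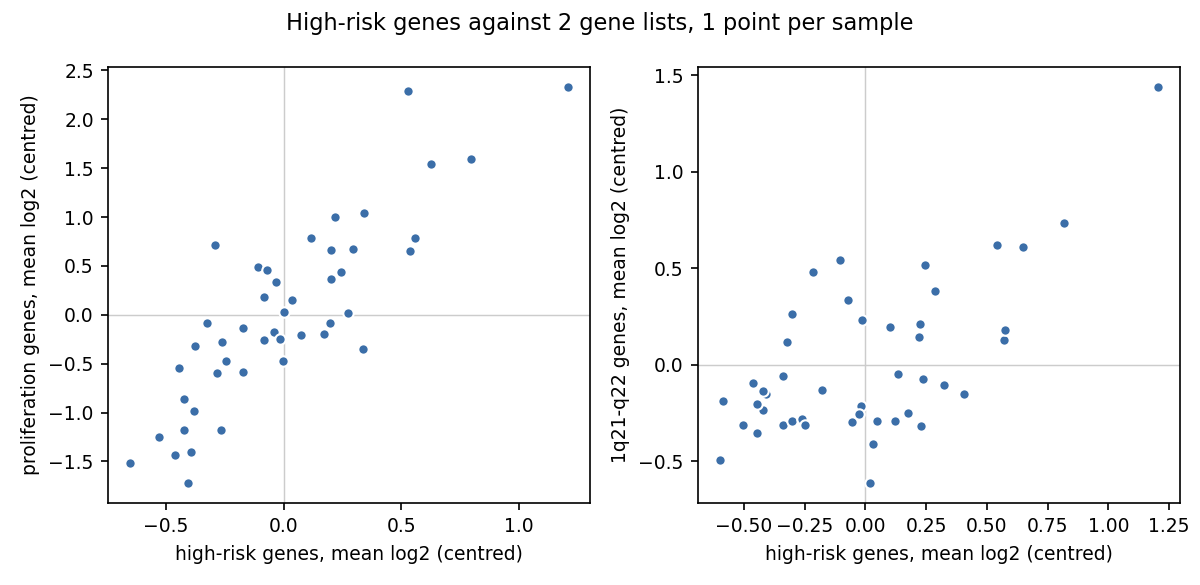
Mean centred log2 signal of the GEP-70 high-risk genes (x axis) against that of the proliferation genes (left) and of the 1q21-q22 genes (right), 1 point per sample (n = 46), shared genes left out. The points follow an r of 0.852 on the left and 0.639 on the right, where r is 0.451 without the 2 samples farthest from the median on the x axis.

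Low-risk genes ran against both lists. Their score had an r of -0.566 with the high-risk genes (adjusted permutation p = 0.00024; rho -0.521, permutation p = 0.00017; -0.488 without 2 samples) and -0.454 with proliferation (adjusted permutation p = 0.00797; rho -0.461, permutation p = 0.00158; -0.433 without 2 samples). With arrays centred on their median these values were -0.0779 (adjusted p = 0.767) and -0.155 (adjusted p = 0.558). Proliferation and respiratory chain genes had an r of 0.375 (adjusted permutation p = 0.0363; rho 0.275, permutation p = 0.0654), which rested on the 2 farthest samples (0.131 without them).

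CRBN, which encodes cereblon, the protein that lenalidomide binds, had a log2 signal of 11.86 ± 0.68 (SD, n = 46) and varied with IRF4, a factor downstream of its drug-induced substrates. Their r was 0.385 (adjusted permutation p = 0.0332), rho 0.431 (permutation p = 0.00311) and r without 2 samples 0.407. With the mean over each gene's probe sets it was 0.144 (adjusted p = 0.452). CRBN had an r of 0.217 with IKZF1 and 0.218 with IKZF3 (adjusted permutation p = 0.269 for both; rho 0.203 and 0.233, permutation p = 0.175 and 0.119), the substrates Ikaros and Aiolos. Its r was -0.189 with proliferation (adjusted permutation p = 0.333; rho -0.240, permutation p = 0.109) and -0.273 with high-risk genes (adjusted permutation p = 0.203; rho -0.319, permutation p = 0.0309). Without 2 samples the last was -0.437 (adjusted p = 0.0127).

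Of 24 relations computed, the 7 above with an adjusted p under 0.05 were called. The 13 not yet given had adjusted permutation p from 0.269 to 0.718. Proliferation had an r of -0.144 with the long arm of chromosome 13, -0.179 with plasma cell identity, 0.0546 with the unfolded protein response, 0.162 with ribosome biogenesis, 0.242 with cancer-testis antigens, -0.132 with NF-kB targets, -0.0873 with interferon response and -0.102 with erythroid markers. The rho values were -0.0763, -0.228, 0.108, 0.172, 0.205, -0.131, -0.0188 and -0.0855, with permutation p from 0.130 to 0.901. Plasma cell identity had an r of 0.105 with monocyte, 0.212 with granulocyte and 0.0743 with B cell markers, high-risk genes -0.214 with granulocyte markers, and NF-kB targets 0.236 with monocyte markers. Their rho values were 0.145, 0.181, 0.0172, -0.171 and 0.125, with permutation p from 0.228 to 0.909. The labels give no array batches or dates, so no relation was computed within batches.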

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

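Of 361 values that answer a comparison, 335 kept their side of the threshold under the alternatives. Of the others, 15 were counts that moved by over 1.5 times, 7 lost the call and 4 gained it. Most relations between scores were not called to begin with, so the 335 do not describe the called ones. The 7 lost calls were of high-risk with low-risk genes, low-risk genes with proliferation, proliferation with the respiratory chain, and CRBN with IRF4. For named genes 467 of 568 values kept their side, 99 lost the call and 2 lost it with the sign reversed. Of 25 genes named for the GEP-70 score, 4 kept it with proliferation as a covariate, 8 without the 2 farthest samples, 16 with members scaled to unit SD, 19 with no filter on dim genes and 21 with other-cell markers as a covariate, and 18 of 22 did without _x_at and _s_at probe sets. For proliferation 13 of 25 kept it without the 2 farthest samples and 17 of 23 with the mean over probe sets, and in the other settings at most 3 named genes lost it. For lists 599 of 653 values kept their side of the threshold, 43 lost the call and 11 gained it. Most lists were not called to begin with, so this share does not describe the called ones. In 11 alternatives run for both scores, the GEP-70 calls of proliferation and 1q21-q22 genes were kept in all 11. The call was kept in 10 for proteasome, 9 for ribosomal proteins, 7 for monocyte and 6 each for granulocyte and stromal genes. With proliferation the monocyte and stromal calls were kept in 6 each. All of these used the preset correlation. With an estimated correlation camera lost the 1q21-q22 call with the GEP-70 score (adjusted p = 0.101). It kept that of proliferation genes (adjusted p = 0.00126). Of the values that kept their side, 72 for lists or pairs changed sign without being called in either setting. Counts of samples 8-fold above a median stayed within 1.5 times in 121 of 147 cases. The exceptions below are grouped by setting, and the cause was not tested. With arrays centred on their median, 156 genes fell with the partial GEP-70 score and 1343 rose with proliferation. In that setting r was -0.0779 between high-risk and low-risk genes, -0.155 between low-risk genes and proliferation, 0.368 between proliferation and ribosome biogenesis, and 0.396 and 0.393 between CRBN and IKZF1 and IKZF3. With the mean over probe sets, r was 0.344 for proliferation and the respiratory chain and 0.144 for CRBN and IRF4. Without _x_at and _s_at probe sets, 243 genes rose and 204 fell with the GEP-70 score, 2 lists were called with the GEP-70 score (proliferation and 1q21-q22) and 4 with proliferation (high-risk, low-risk, 1q21-q22 and the respiratory chain), 10 of the 15 genes still measured had a sample 8-fold above the median, r of proliferation and the respiratory chain was 0.340, and the GEP-70 slope of GAS1 was -0.0125.

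Without the 2 samples farthest from the median, 106 genes rose and 63 fell with the GEP-70 score, 4 lists were called, and 144 genes rose and 34 fell with proliferation, a setting with fewer samples. There r was 0.131 for proliferation and the respiratory chain and -0.437 for CRBN and high-risk genes. With other-cell markers as a covariate 5 lists were called with the GEP-70 score, and r of proliferation and the respiratory chain was 0.355. With proliferation as a covariate 8 genes rose and 14 fell with the GEP-70 score and the slope of KIT was 0.12. Leaving out each sample in turn, chosen after seeing the data, gave 220 to 565 rising and 155 to 418 falling genes for the GEP-70 score, and 151 to 412 and 32 to 211 for proliferation. The lowest totals, 375 and 183, came without the sample with the highest proliferation score. Dim probe sets limit the values of low genes, since signal over background was not given.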

Other observations

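The tests of other-cell markers, and quantile normalization in the chromosome comparison, were chosen after the results were seen. Genes of every autosome moved together across the samples more than random genes of the same mean expression: the mean pairwise correlation within each of the 22 chromosomes exceeded that of all 500 random sets. The excess over random sets was 0.0953 for chromosome 13, 0.0739 for chromosome 14, 0.0656 for chromosome 15, 0.0620 for chromosome 9, 0.0523 for chromosome 11 and 0.0512 for chromosome 22. It was 0.00988 for chromosome 10 and 0.0131 for chromosome 12. Immunoglobulin genes were left out of this comparison. Genes are not independent replicates, and these values describe the 46 samples.

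A candidate explanation for this pattern is the gain of odd-numbered chromosomes that marks hyperdiploid myeloma (3, 5, 7, 9, 11, 15, 19 and 21). The median excess of these 8 chromosomes was higher by 0.0176 than that of the other 14, which missed the threshold set beforehand (one-sided permutation p = 0.0533), so this test left it open. After quantile normalization, an added alternative, the difference was 0.0195 (permutation p = 0.00994) and cannot replace the planned result. Each chromosome's score was centred on the mean over all autosomes of the same sample, which by itself pulls pairs below 0. The scores of the 8 chromosomes had a mean correlation with each other of 0.128, as gains in the same samples would give. Random sets of 8 autosomes had a mean of -0.0399 (one-sided permutation p = 0.00891). Single pairs ranged from -0.132 to 0.532 and 8 of 28 were negative, to which the centring may add. Copy number was not measured here, and chromosomes 13, 14 and 22, which are outside this set, show that other sources could add to the pattern.

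Many genes varied with each score, 887 with the partial GEP-70 score and 523 with proliferation. As a test of chance pairing of score and sample, 1 of 100 orders, the real one, gave as many genes for both. The highest of the others gave 3. Each score is built from genes of the same arrays, so genes correlated with its members follow it in the real order alone. The shuffles thus bound the false calls of the test and exclude no source of shared variation. RNA quality, RNA of the cell types in the other-cell covariate, and array scaling are argued against as the whole cause for the GEP-70 score. That covariate held monocyte, granulocyte, erythroid and T and NK markers, and stromal and megakaryocyte RNA was not examined this way. With the 3'/5' ratio as a covariate the count was 107.6% of the original, with other-cell markers 84.7% and after quantile normalization 91.0%. With arrays centred on their median 594 rose and 156 fell, so the directions called did depend on scaling. The count is a coarse measure, since it also moves with single samples. Proliferation stays open as the source of most GEP-70 calls, since 8 rising and 14 falling genes were left with it as a covariate and 4 of the 25 named genes kept the call. The scores had an r of 0.764 with each other, so the covariate also lowers the precision of each slope. Lost calls alone therefore do not show that the slopes shrank. The count depends on single samples, with a total of 375 without the sample with the highest proliferation score. All 887 genes kept the sign of their slope without the 2 farthest samples. Their slopes kept a median of 80.5% of their size per SD of the remaining samples, which is a smaller unit. Those genes were chosen in data that include the remaining samples, so neither value is an independent sign of stability. Apart from proliferation and RNA of the cell types in the other-cell covariate, no biological explanation was tested.

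Markers of other marrow cells were lower where the partial GEP-70 score was higher, which could come from a smaller share of non-plasma cells in those samples, although the CD138 selection should remove such cells. Of the 6 lists 5 had a negative median slope, and T and NK cell markers had a median of 0.02. Their mean slope was -0.07 with an SE of 0.08, and camera gave them a falling direction. The exception thus rests on the choice of the median over the mean. The 10 T and NK genes were dim (mean log2 signal from 5.31 to 7.86). So were CD14 (5.57), CSF1R (7.11), MPO (6.62) and LTF (7.61) of the falling lists, although LYZ (10.56) and S100A8 (12.39) were not. Dim signal therefore does not clearly set the T and NK list apart, and this explanation stays open. Array scaling is argued against as the whole cause, since the 5 lists kept at least 87.9% of their median slope after quantile normalization and after median centring, and the 3 called lists stayed called in both, although all 3 calls were lost with an estimated correlation (adjusted p = 0.395, 0.546 and 0.395), without the 2 farthest samples and without _x_at and _s_at probe sets. A first bound for scaling, 6 negative lists after quantile normalization, could not be met because 5 were negative before it. Of the 54 genes in these lists 0 were in another list, and how many of them plasma cells also express was not determined.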
